A study of Homo sapiens with 24 samples.

How the data were processed

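RNA sequencing measured gene expression in 24 libraries of human monocyte-derived macrophages, in 8 groups of 3. Per the labels, cells kept in M-CSF at 10 ng/ml were left untreated or given interferon alpha (IFN-alpha, 25 ng/ml), tumor necrosis factor (TNF, 10 ng/ml) or both for 24 hours, and each of these 4 conditions was then studied without or with lipopolysaccharide (LPS, 10 ng/ml) for 3 hours. The labels number the libraries 1 to 3 in each group and do not say which libraries share a donor, so p-values measure the spread between these libraries. In each treatment the column without a number was taken as replicate 1, because columns 2 and 3 were present.

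The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for 21917 rows. Per the submitters' processing notes, FastQC, Trim Galore, STAR (version 2.5.2b), Cufflinks (version 2.2.1) and the human build hg19 were used. The order of these tools, the annotation and the scaling between libraries are not given in the sources used here. FPKM values are not read counts, so the depth of each library is unknown and no interval from counting error can be given. Of the table's rows, 28 carried a date in place of a gene symbol and 83 were Y-linked genes or XIST; both were left out, which left 21806 genes, named as in the table. The TNF gene itself was not analysed here. Genes of the MHC region were also left out as an alternative, because reads of near-identical genes there can be split unevenly.

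Values were taken as log2(FPKM + 1), so a fold change understates the change of a gene with a low level. The 11298 genes with FPKM of at least 1 in at least 3 libraries were tested. One coefficient per group was fitted over all 24 libraries with limma (version 3.58.1; lmFit and eBayes with a variance trend) in R 4.3.3, in 12 pairwise comparisons and 5 interactions, that is, differences between effects. The limma moderated test was two-sided, with Benjamini-Hochberg adjustment over genes within a comparison, and a gene was called at an adjusted p under 0.05. All fold changes below are log2 values on this scale.

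In each pairwise comparison the 6 largest increases and the 6 largest decreases were named, among called genes with a mean of at least 5 FPKM in the higher group and all 3 libraries of one group above the 3 of the other. Chance separates 3 libraries from 3 in this way in 10% of splits. In interactions the 6 largest effects in each direction were named. Some genes that these rules pick are not reported here. A panel of 33 genes was fixed too, of which 32 were in the table, and so were 40 gene lists, from which up to 4 called genes with the largest effects were named. Groupings, comparisons, tests, lists and alternatives were fixed before the data were examined, except where stated. The exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so single genes rest on the limma model alone.

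The 34 lists with at least 5 tested genes were tested with camera (limma), at a preset correlation of 0.01 between genes, in 578 tests with 1 adjustment over all of them. Of these, 192 were called, and 51 of the 192 were also called with the correlation estimated from the data, by camera. A list is said to have risen or fallen only where both versions were called. Lists can share genes, as IDO1 is named below under different lists. Calls of several lists in a comparison therefore need not be separate responses. The fry test, which asks only whether a list's genes moved one way on balance, called 293.

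Genes induced by LPS were those called in LPS against untreated with a log2 fold change of at least 1. Among them, genes lower with TNF were called lower by at least 1 in TNF+LPS against LPS, and of those, genes higher again with IFN-alpha were called higher by at least 1 in IFN+TNF+LPS against TNF+LPS. This last selection shares the TNF+LPS libraries between its steps, so the selection was repeated with 1 replicate number held out.

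Libraries with the same number deviated together from their group means: over the 84 same-numbered pairs the lowest correlation was 0.289 and the median 0.638, and all 24 libraries correlated best with a library of their own number. The pairing thus comes from the data. A fit with replicate number as a block was made beside the gene calls, the LPS-induced classes and the list tests at the preset correlation. List tests with an estimated correlation and fry were run without the block, so they were not checked for the pairing. With numbers 2 and 3 alone the lowest correlation was -0.0401 and the median 0.399, so the pairing rests in part on the libraries numbered 1, which stood apart on component 3 (12.9% of the variance). Within groups, libraries correlated with each other between 0.903 and 0.987 (Pearson's r across genes of log2 values), and at most 0.257% of all genes had an identical value of at least 1 in a pair of libraries.

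Other alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median centring, quantile normalization, no variance trend, only the groups compared, a size threshold (without it for the LPS-induced classes), fry and the estimated correlation, and each library left out in turn. Alternatives chosen after seeing the data were scaling every library to the same FPKM sum, only replicate numbers 2 and 3, and leaving out the MHC region. Tests on simulated data, with 200 of 11298 genes changed, recovered 10.5% of 1.5-fold, 65.0% of 2-fold and 95.0% of 4-fold changes in LPS against untreated, with 12.5%, 5.11% and 4.52% of the calls false. For the interaction of TNF with LPS the recovered shares were 0, 20.0% and 84.0%. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2 in untreated cells. Noise was drawn independently for each library, without the shared deviation by replicate number. The shares therefore need not hold for genes at low levels or for the real libraries.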

Results

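Gene expression was measured in 24 libraries of human macrophages, 3 in each of 8 groups: untreated, TNF, IFN-alpha and IFN-alpha with TNF, each without and with LPS, a bacterial membrane component that TLR4 recognises. The design asks how macrophages that have met TNF, an inflammatory cytokine, or IFN-alpha, an antiviral cytokine, or both, respond to LPS. In the text, IFN stands for IFN-alpha in group names. A gene is called when limma gave an adjusted p under 0.05, and levels are means ± SD of the deposited FPKM over 3 libraries. Component 1 of the log2 values carried 39.6% of the variance and component 2 carried 21.5%. Libraries relabelled at random gave as many gene list calls at the preset correlation in 60 of 100 draws. With an estimated correlation only the real labels did, in 1 of 100. Such draws exchange treatments, so they favor neither version of the test and cannot weigh chance for a single list. The depth of the libraries is unknown, and the summed FPKM differed between groups, from 315831 ± 14420 (SD, n = 3) with TNF and 328387 ± 8284 in untreated cells to 670281 ± 16155 with LPS and 710067 ± 76066 with IFN-alpha and LPS. The sum was 345070 ± 21826 with IFN-alpha, 350181 ± 22132 with IFN-alpha and TNF, 446815 ± 18678 with TNF and LPS, and 619594 ± 83099 with all 3.

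**Figure D1:**
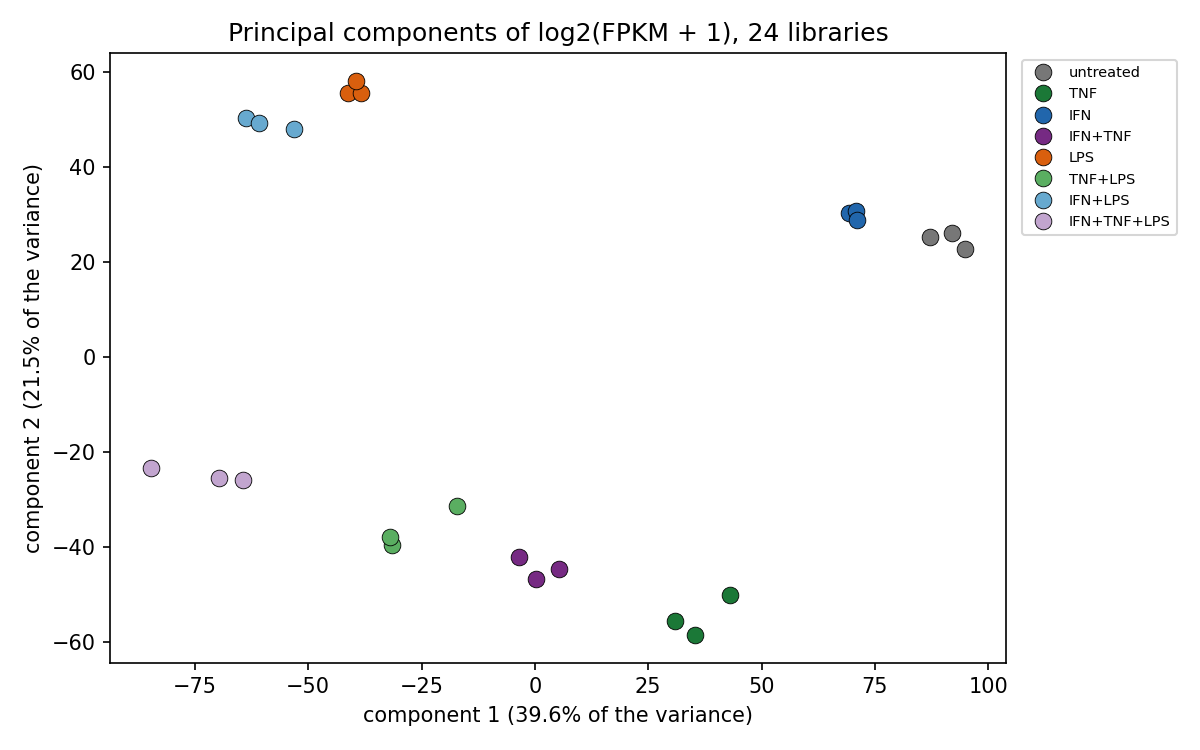
Each point is 1 of the 24 libraries, placed by components 1 and 2 of log2(FPKM + 1), with the share of the variance on each axis and a color for each of the 8 groups. The 4 groups given TNF lie below 0 on component 2 and the other 4 above it.

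LPS alone raised genes of inflammation such as IRG1, IL1B and IL6. IRG1 (ACOD1), the enzyme that makes itaconate, rose by 11.42 (SE 0.314, adjusted p = 4.01e-15) on the log2 scale, and IL1B, which encodes interleukin 1 beta, rose from 2.38 ± 0.197 FPKM (SD, n = 3) to 7035 ± 2103 FPKM. IL6, encoding a cytokine of fever and the acute phase, rose from 0.20 ± 0.0721 FPKM to 941 ± 259.5 FPKM. The T cell attracting chemokine genes CXCL10 and CXCL11 rose by 10.62 and 10.13, CCL4 by 9.89, and TNIP3, an inhibitor of NF-kB signalling, by 9.72. The largest decreases were in the chemokine receptor CXCR4 (-5.84), KLHDC8B (-5.49), PDK4, which restrains the use of glucose in mitochondria (-5.21), RAB42 (-4.97), the TLR4-related receptor CD180 (-4.90) and FAM78A (-4.44).

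Feedback inhibitors of NF-kB and MAP kinases rose with LPS: 27 of 31 tested genes were called higher and 1 lower (27 and 1 adjusted over the list alone, adjusted p = 3.63e-13, adjusted p = 0.0351 with an estimated correlation), led by TNIP3, TRAF1 (9.52), the phosphatase DUSP5 (7.59) and TNFAIP3 (7.07), which encodes the deubiquitinase A20. Of guanylate-binding proteins and IRF1 targets, 20 of 25 tested genes were called higher (20 adjusted over the list alone, adjusted p = 1.18e-10, adjusted p = 0.0187 with an estimated correlation), among them IDO1, which breaks down tryptophan (9.13), and GBP1 (8.19). Enzymes of immunometabolism rose (adjusted p = 2.06e-06, adjusted p = 0.0187 with an estimated correlation): 13 of 18 tested genes were called higher and 2 lower (13 and 2 adjusted over the list alone), with GCH1, an enzyme of tetrahydrobiopterin synthesis, at 7.51 and the mitochondrial superoxide dismutase SOD2 at 6.02. In the list of inflammasome and cell death genes, 25 of 30 tested genes were called higher and 3 lower (26 and 3 adjusted over the list alone, adjusted p = 5.04e-08, adjusted p = 0.0187 with an estimated correlation), including IL1A (7.52) and the survival gene BCL2A1 (6.98). In the list of ligands that steer T cells, which also holds the chemokine receptor CCR7, 14 of 17 tested genes were called higher and 2 lower (14 and 2 adjusted over the list alone, adjusted p = 8.82e-06, adjusted p = 0.0462 with an estimated correlation), with SLAMF7 at 8.75, CD274, which encodes PD-L1, at 7.83, and the co-stimulatory ligand CD80 at 5.87. TNF receptor and response genes rose (16 of 20 tested genes higher and 1 lower, 16 and 1 adjusted over the list alone, adjusted p = 1.23e-07, adjusted p = 0.0391 with an estimated correlation). So did the NF-kB subunits, with 5 of 5 tested genes higher, 5 adjusted over the list alone, adjusted p = 3.28e-05, adjusted p = 0.0468 with an estimated correlation.

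Interferon-stimulated genes were called at the preset correlation only (57 of 59 tested genes higher, 58 adjusted over the list alone, adjusted p = 9.13e-26, adjusted p = 0.175 with an estimated correlation), with IFIT2 at 8.23, OASL at 8.06 and ISG15 at 6.84. Inflammatory cytokines were called in the same way (19 of 23 tested genes higher, 19 adjusted over the list alone, adjusted p = 1.29e-07, adjusted p = 0.0793 with an estimated correlation). So were chemokines (20 of 28 tested genes higher, 20 adjusted over the list alone, adjusted p = 9.01e-09, adjusted p = 0.0706 with an estimated correlation). The scavenger receptor CD163 (-0.22, adjusted p = 0.775), the mannose receptor MRC1 (-0.37, adjusted p = 0.124) and TLR4 itself (0.52, adjusted p = 0.180) were not called. CD14, the co-receptor for LPS, was lower (-1.37, SE 0.293, adjusted p = 0.000566). In all, 6043 genes were called, 3014 higher and 3029 lower, of 11298 tested. With every library scaled to the same FPKM sum, chosen after seeing the data, the higher share of calls went from 49.9% to 15.4%, because that scaling lowers the median of all genes by itself, from -0.0237 to -0.80. Over the 10 other settings compared the share went from 41.4% (median centring) to 58.8% (the filter at 5 FPKM).

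**Figure D2:**
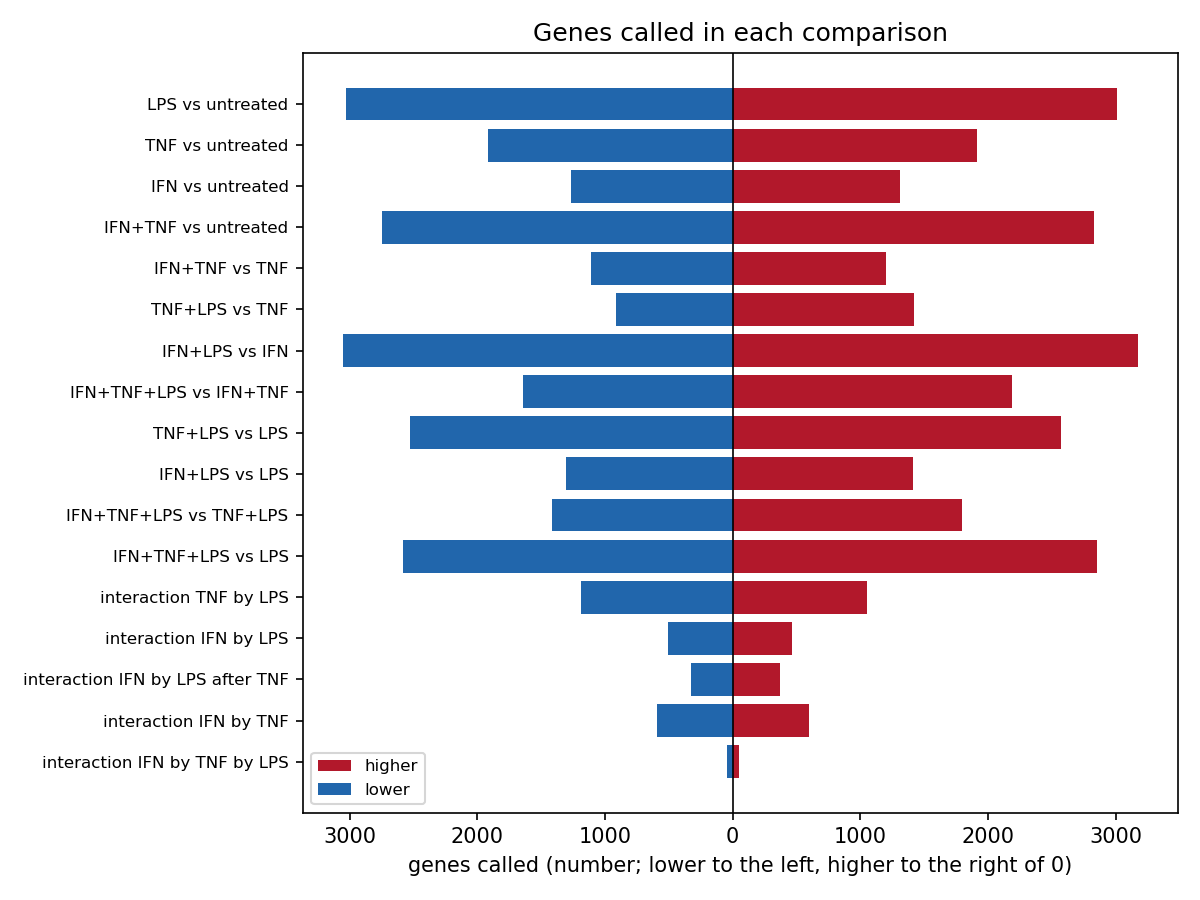
Bars give the number of genes called higher (right) and lower (left) in each of the 12 pairwise comparisons and 5 interactions. LPS called 6043 genes in untreated cells and 2336 in cells given TNF first, and the interaction of all 3 treatments called 100.

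TNF alone, after 24 hours, lowered genes of macrophage identity and raised NF-kB feedback genes. SEPP1 (SELENOP), a selenium carrier, fell from 1441 ± 190.5 FPKM (SD, n = 3) to 1.87 ± 2.02 FPKM, and the folate receptor gene FOLR2 from 444 ± 179 FPKM to 0.410 ± 0.173 FPKM. DHRS9 (-6.69), RNASE1 (-6.64), HS3ST2 (-6.60) and MS4A6A (-6.58) made up the rest of the 6 largest decreases. The largest increases were in the metallothionein genes MT1H (8.66), MT1G (7.79) and MT1M (7.48) and the metallothionein pseudogene MT1P2 (8.15), in CLU, which encodes the chaperone clusterin (7.86), and in IL1B (7.78). Metallothionein genes are near-identical, so reads may be split among them and single values are uncertain.

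Genes of macrophage identity and scavenging fell: 4 of 40 tested genes were called higher and 23 lower (4 and 23 adjusted over the list alone, adjusted p = 6.39e-08, adjusted p = 0.00126 with an estimated correlation), with the lectin CLEC10A at -6.14, the coagulation factor gene F13A1 at -6.11 and MRC1 at -2.52. Feedback inhibitors rose (23 of 31 tested genes higher, 25 adjusted over the list alone, adjusted p = 2.44e-12, adjusted p = 0.0391 with an estimated correlation), with TNFAIP3 at 3.87, NFKBIA, the inhibitor of NF-kB, at 3.11, and SOCS3 at 4.04. IRAK3, an inhibitor of TLR signalling, rose by 1.76. Enzymes of immunometabolism rose (13 of 18 tested genes higher and 2 lower, 14 and 3 adjusted over the list alone, adjusted p = 9.8e-07, adjusted p = 0.0187 with an estimated correlation), including IDO1 (7.09), NAMPT, an enzyme of NAD synthesis (4.31), and SOD2 (4.12). Nuclear genes of oxidative phosphorylation fell by a small step, with a median of -0.31: 16 of 36 tested genes were called lower (16 adjusted over the list alone, adjusted p = 5.55e-06, adjusted p = 0.0433 with an estimated correlation), UQCRC2 and UQCRQ of complex III at -0.98 and -0.95.

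Metallothioneins and metal handling genes were called at the preset correlation only (14 of 20 tested genes higher and 3 lower, 14 and 3 adjusted over the list alone, adjusted p = 1.05e-05, adjusted p = 0.0888 with an estimated correlation). Interferon-stimulated genes were called lower in the same way (2 of 59 tested genes higher and 30 lower, 2 and 32 adjusted over the list alone, adjusted p = 3.28e-05, adjusted p = 0.721 with an estimated correlation). Examples were SIGLEC1 (-2.86) and OAS2 (-2.62). Among pattern recognition receptors, 12 of 26 tested genes were called higher and 4 lower (14 and 5 adjusted over the list alone, adjusted p = 0.0270, adjusted p = 0.468 with an estimated correlation), with the C-type lectins CLEC4D (5.57), CLEC4E (5.49) and CLEC6A (5.25). IL6 was hardly expressed, at 0.283 ± 0.0874 FPKM, and was not called (0.10, adjusted p = 0.916). Markers of other blood cells moved too: NKG7, a natural killer cell marker, was at 583 ± 210.0 FPKM with TNF against 3.49 ± 2.57 FPKM. Neutrophil markers had a median of 91.8 FPKM with TNF and 5.13 FPKM in untreated cells, with S100A9, also made by monocytes, highest at 2763 FPKM and 924 FPKM. In all, 3828 genes were called, 1910 higher and 1918 lower.

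IFN-alpha alone raised every tested interferon-stimulated gene on the list. IFITM1, which restricts virus entry, rose by 8.38 (SE 0.493, adjusted p = 5.69e-10), the cytidine deaminase APOBEC3A by 6.51, IFI27 by 6.14, and CXCL10 from 9.58 ± 6.95 FPKM (SD, n = 3) to 923 ± 549.8 FPKM. The galectin gene LGALS2 (7.12) and the chemokine CCL8 (6.0) completed the 6 largest increases. The apolipoprotein genes APOC1 (-5.03) and APOE (-4.94), HS3ST2 (-4.46), PPAP2B (-4.46) and CYP27A1, which makes an oxysterol from cholesterol (-4.15), were lower.

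Of interferon-stimulated genes, 59 of 59 tested genes were called higher (59 adjusted over the list alone, adjusted p = 3.28e-55, adjusted p = 0.0433 with an estimated correlation), with IFIT1 at 5.83, ISG15 at 5.62 and MX1 at 3.80. Guanylate-binding proteins and IRF1 targets rose (16 of 25 tested genes higher and 1 lower, 16 and 1 adjusted over the list alone, adjusted p = 4.79e-08, adjusted p = 0.0351 with an estimated correlation), for example SERPING1, the C1 inhibitor (4.62), and GBP5 (4.07). Sensors of microbial nucleic acid led a rise of pattern recognition receptors (16 of 26 tested genes higher, 17 higher and 1 lower adjusted over the list alone, adjusted p = 3.11e-09, adjusted p = 0.0355 with an estimated correlation): AIM2 (4.57), DDX58, which encodes RIG-I (3.60), and IFIH1, which encodes MDA5 (3.26). Inflammasome and cell death genes rose (19 of 30 tested genes higher and 3 lower, 20 and 4 adjusted over the list alone, adjusted p = 8.5e-08, adjusted p = 0.0198 with an estimated correlation), among them TNFSF10, which encodes TRAIL (5.68), and ZBP1 (5.25). The IRF family rose too (5 of 9 tested genes higher, 6 adjusted over the list alone, adjusted p = 0.00104, adjusted p = 0.0391 with an estimated correlation), with IRF7, the amplifier of interferon production, at 4.12 and IRF1 at 1.55. Nuclear genes of oxidative phosphorylation fell with a median of -0.40 (1 of 36 tested genes higher and 17 lower, 1 and 20 adjusted over the list alone, adjusted p = 6.33e-06, adjusted p = 0.0433 with an estimated correlation). In all, 2580 genes were called, 1311 higher and 1269 lower, and 4018 with replicate number as a block.

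IFN-alpha and TNF were also given together without LPS. Against untreated cells IDO1 rose by 9.82 (SE 0.299, adjusted p = 1.4e-14), CCL8 by 8.01, TNFAIP6 by 7.86, CCL5 from 3.61 ± 2.38 FPKM (SD, n = 3) to 960.4 ± 261 FPKM, CCR7, the receptor that guides cells to lymph nodes, by 7.50, and MT1M by 7.48. SEPP1 (-9.78), FOLR2 (-8.32), F13A1 (-8.07), S100A4 (-7.11), the scavenger receptor STAB1 (-7.09) and the lysosomal lipase LIPA (-7.08) were lowest. Macrophage identity genes fell (3 of 40 tested genes higher and 28 lower, 4 and 29 adjusted over the list alone, adjusted p = 8.5e-08, adjusted p = 0.00126 with an estimated correlation). CD163 was at 125 ± 70.4 FPKM against 823 ± 411 FPKM. Enzymes of immunometabolism rose (14 of 18 tested genes higher, 15 adjusted over the list alone, adjusted p = 7.23e-08, adjusted p = 0.0171 with an estimated correlation). Feedback inhibitors rose (27 of 31 tested genes higher, 27 adjusted over the list alone, adjusted p = 9.85e-12, adjusted p = 0.0433 with an estimated correlation). Inflammasome and cell death genes rose (22 of 30 tested genes higher and 2 lower, 23 and 2 adjusted over the list alone, adjusted p = 2.42e-06, adjusted p = 0.0351 with an estimated correlation). T cell ligands rose (12 of 17 tested genes higher and 1 lower, 12 and 1 adjusted over the list alone, adjusted p = 4.57e-06, adjusted p = 0.0433 with an estimated correlation), with CD80 at 6.22 and CD274 at 5.67. Nuclear genes of oxidative phosphorylation fell (1 of 36 tested genes higher and 22 lower, 1 and 23 adjusted over the list alone, adjusted p = 6.33e-06, adjusted p = 0.0433 with an estimated correlation). In all, 5574 genes were called, 2828 higher and 2746 lower.

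Against TNF alone, the added IFN-alpha again raised the interferon-stimulated genes (59 of 59 tested genes higher, 59 adjusted over the list alone, adjusted p = 1e-71, adjusted p = 0.0351 with an estimated correlation). CCL8 (8.14), APOBEC3A (7.57), RSAD2, which encodes viperin (7.46), IFI27 (7.40), CXCL10 (7.26) and IFITM1 (7.09) rose most. The neutrophil chemokine CXCL5 (-4.47), NKG7 (-4.36), APOC1 (-4.16), KCNJ15 (-4.12) and the formyl peptide receptor FPR1 (-3.92) were lower. The IRF family rose (6 of 9 tested genes higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 5.77e-05, adjusted p = 0.0187 with an estimated correlation), with IRF4 at 3.06 and IRF5 at 2.13. So did guanylate-binding proteins and IRF1 targets (14 of 25 tested genes higher and 2 lower, 17 and 2 adjusted over the list alone, adjusted p = 4.18e-08, adjusted p = 0.0351 with an estimated correlation). Inflammasome and cell death genes rose as well (13 of 30 tested genes higher and 1 lower, 15 and 3 adjusted over the list alone, adjusted p = 3.82e-06, adjusted p = 0.0355 with an estimated correlation). T cell ligands rose too (8 of 17 tested genes higher, 12 adjusted over the list alone, adjusted p = 4.12e-06, adjusted p = 0.0433 with an estimated correlation). Genes of glycolysis were called lower at the preset correlation only (2 of 23 tested genes higher and 12 lower, 2 and 13 adjusted over the list alone, adjusted p = 0.000482, adjusted p = 0.0855 with an estimated correlation), with the hexokinase HK3 at -2.90 and LDHA at -1.19. In all, 2314 genes were called, 1202 higher and 1112 lower, and 3865 with the block but 1293 with only the groups compared. Neutrophil markers had a median of 13.1 FPKM against 91.8 FPKM with TNF, a list that camera did not call (adjusted p = 0.111) and fry did (adjusted p = 0.0405). The higher share was 51.9%, 35.5% with equal FPKM sums, and from 43.2% (median centring) to 57.5% (the 2-fold threshold) over the 10 other settings.

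After TNF, LPS still switched on interferon-stimulated genes, while IL6 and IL12B stayed far below their levels with LPS alone. IFIT2 (8.70, SE 0.621, adjusted p = 5.24e-09), OASL (8.48), ISG15 (8.15), IFIT3 (7.61), IRG1 (7.49) and RSAD2 (7.40) rose most in TNF+LPS against TNF. MYCL1 (-3.30), the efferocytosis receptor MERTK (-2.45), the TGF-beta receptor TGFBR2 (-2.40), NT5DC2 (-2.35), the proton channel HVCN1 (-2.27) and IQCD (-2.23) were lowest. IL6 reached 18.7 ± 16.3 FPKM (SD, n = 3) here against 941 ± 259.5 FPKM with LPS alone, and IL12B 0.103 ± 0.0764 FPKM against 18.1 ± 2.44 FPKM. Interferon-stimulated genes rose (57 of 59 tested genes higher, 58 adjusted over the list alone, adjusted p = 3.62e-61, adjusted p = 0.0391 with an estimated correlation). Guanylate-binding proteins and IRF1 targets also rose (19 of 25 tested genes higher, 19 adjusted over the list alone, adjusted p = 2.44e-12, adjusted p = 0.0187 with an estimated correlation). Inflammasome and cell death genes rose (18 of 30 tested genes higher and 1 lower, 21 and 1 adjusted over the list alone, adjusted p = 1.16e-09, adjusted p = 0.0174 with an estimated correlation). The IRF family followed (6 of 9 tested genes higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.000523, adjusted p = 0.0351 with an estimated correlation). Immunometabolic enzymes rose (12 of 18 tested genes higher and 1 lower, 12 and 1 adjusted over the list alone, adjusted p = 1.81e-06, adjusted p = 0.0187 with an estimated correlation). TNF receptor and response genes rose (12 of 20 tested genes higher and 1 lower, 14 and 1 adjusted over the list alone, adjusted p = 8.48e-07, adjusted p = 0.0462 with an estimated correlation). In all, 2336 genes were called, 1423 higher and 913 lower, and 3832 with the block but 1187 with only the groups compared. The higher share of 60.9% was 44.9% with median centring and 16.4% with equal FPKM sums. It was 68.0% with the filter at 5 FPKM, and over the 10 settings other than equal sums it went from 42.1% (quantile normalization) to 81.3% (the 2-fold threshold).

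Set beside LPS alone, cells given TNF before LPS had lower levels of several cytokines and chemokines. CXCL11 (-7.24, SE 0.680, adjusted p = 1.21e-07), CXCL10 (-6.55), CXCL9 (-5.65), IL6 (-5.96), IL27 (-4.67) and IL12B (-4.11) were lower. So were SEPP1 (-8.86), FOLR2 (-8.23), RNASE1 (-7.42) and F13A1 (-6.59), and macrophage identity genes fell (3 of 40 tested genes higher and 23 lower, 4 and 24 adjusted over the list alone, adjusted p = 4.12e-06, adjusted p = 0.00499 with an estimated correlation). MT1H (7.92), MT1P2 (7.32), CLU (7.80), PTGES, which makes prostaglandin E (7.21), the inhibitory lectin SIGLEC10 (7.20) and NKG7 (6.71) were higher. Metallothioneins and metal handling genes were called at the preset correlation only (14 of 20 tested genes higher and 2 lower, 15 and 2 adjusted over the list alone, adjusted p = 0.000353, adjusted p = 0.175 with an estimated correlation). NKG7 was at 505 ± 103 FPKM against 4.62 ± 3.94 FPKM, and neutrophil markers had a median of 113 FPKM against 8.65 FPKM. Of chemokines, 5 of 28 tested genes were called higher and 14 lower (5 and 14 adjusted over the list alone), called at the preset correlation only (adjusted p = 0.0257, adjusted p = 0.586 with an estimated correlation), and not with the block (adjusted p = 0.055). CCL5 was not called (0.78, adjusted p = 0.124), though it was with the block (adjusted p = 0.0382), at 3935 ± 1181 FPKM against 2318 ± 838 FPKM. In all, 5097 genes were called, 2570 higher and 2527 lower. The higher share of 50.4% became 81.8% with equal FPKM sums, and went from 46.9% (the filter at 5 FPKM) to 51.5% (a pseudocount of 0.1) over the 10 other settings.

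The interaction of TNF with LPS tested the difference between the LPS effects with and without TNF. Feedback inhibitors responded less to LPS after TNF (21 of 31 tested genes lower, 21 adjusted over the list alone, adjusted p = 4.71e-18, adjusted p = 0.0187 with an estimated correlation). T cell ligands did so too (2 of 17 tested genes higher and 11 lower, 2 and 13 adjusted over the list alone, adjusted p = 4.92e-07, adjusted p = 0.0351 with an estimated correlation), and so did guanylate-binding proteins and IRF1 targets (14 of 25 tested genes lower, 15 adjusted over the list alone, adjusted p = 1.18e-08, adjusted p = 0.0351 with an estimated correlation). The same held for immunometabolic enzymes (9 of 18 tested genes lower, 9 adjusted over the list alone, adjusted p = 5.94e-07, adjusted p = 0.0187 with an estimated correlation). It held for TNF receptor and response genes (1 of 20 tested genes higher and 13 lower, 1 and 14 adjusted over the list alone, adjusted p = 2.32e-08, adjusted p = 0.0351 with an estimated correlation). NF-kB subunits gave a smaller response as well (5 of 5 tested genes lower, 5 adjusted over the list alone, adjusted p = 1.82e-06, adjusted p = 0.0351 with an estimated correlation). Levels before LPS differed too: NFKBIA was at 754 ± 67.7 FPKM with TNF, 1094 ± 306 FPKM with TNF and LPS and 3339 ± 692 FPKM (SD, n = 3) with LPS. IL1B was at 811 ± 431 FPKM with TNF and 2560.1 ± 1901 FPKM with TNF and LPS. For interferon-stimulated genes this list test was not called (adjusted p = 0.528), nor was ISG15 (1.30, adjusted p = 0.109). In all, 2240 genes were called, 1052 higher and 1188 lower, and 3836 with the block. Positive values made up 47.0% of calls, 82.0% with equal FPKM sums, and from 41.3% (the filter at 5 FPKM) to 54.8% (median centring) over the 10 other settings.

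Across the 1788 genes induced by LPS at least 2-fold, the median LPS effect was 1.84 in untreated cells. It was 0.80 after TNF, 1.60 after IFN-alpha and 0.88 after both. The genes were chosen on the first of these effects, which could raise its median. In a replicate number held out of the selection, the first was between 1.87 and 1.91, no lower than 1.84. The effect after TNF was between 0.79 and 0.83 there, and that after both between 0.81 and 0.99. TNF lowered 558 of these genes at least 2-fold (31.2%), including 12 of the 20 induced chemokines and 18 of the 56 induced interferon-stimulated genes. With equal FPKM sums 182 genes met this definition, and 443 of the 558 were still called lower with TNF. The other 1230 LPS-induced genes were not called at least 2-fold lower with TNF.

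**Figure D3:**
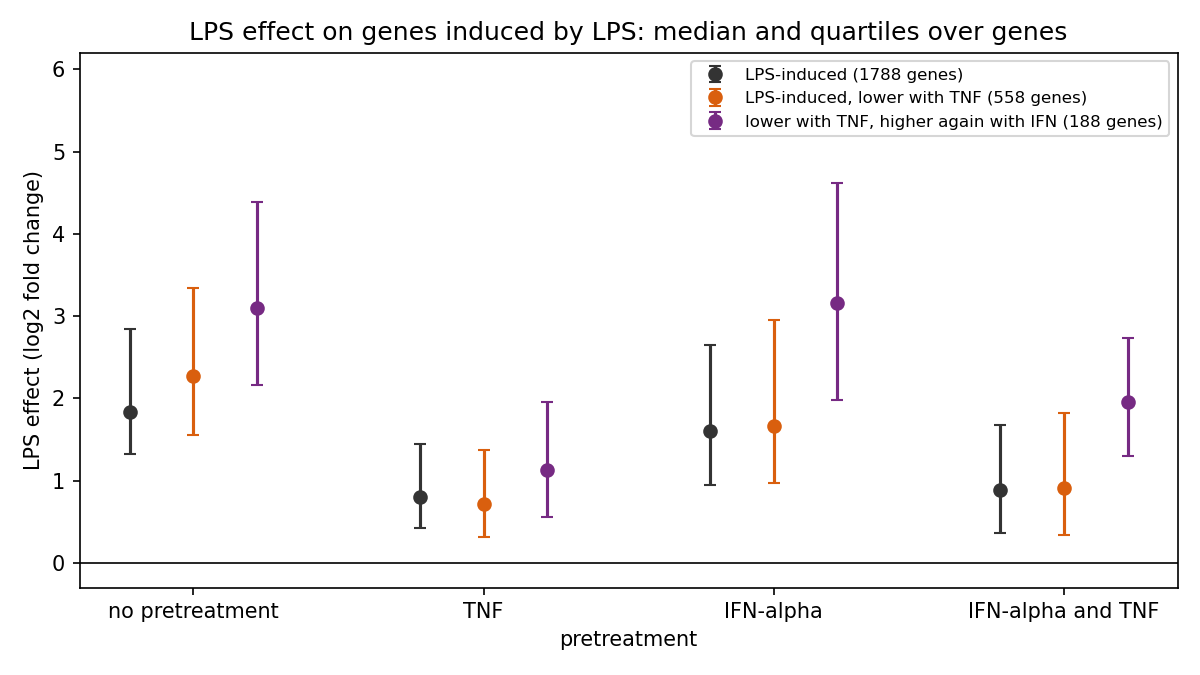
Points are the median and bars the quartiles over genes of the LPS effect (log2 fold change) in cells with no pretreatment, TNF, IFN-alpha or both, for the 1788 LPS-induced genes, the 558 that TNF lowered and the 188 of these that IFN-alpha raised again. The medians of the 188 genes were 3.10, 1.13, 3.16 and 1.96. The 558 and the 188 were chosen on levels in these same libraries. That choice by itself favors a lower value after TNF and, for the 188, a higher value after both.

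After IFN-alpha, LPS still induced inflammatory genes strongly. CCL4 rose by 10.66 (SE 0.519, adjusted p = 4.78e-12), IRG1 by 10.46, BCL2A1 by 10.38, TNIP3 by 9.85, IL6 by 9.55 and IL1B by 9.31. ZFP36L2 (-4.57), the readthrough gene GIMAP1-GIMAP5 (-4.53), PLA2G15 (-4.30), the pseudogene CXCR2P1 (-4.11), TGFBR2 (-4.10) and the transcription factor HHEX (-4.07) were lowest. Feedback inhibitors of NF-kB rose (27 of 31 tested genes higher and 1 lower, 27 and 1 adjusted over the list alone, adjusted p = 1.94e-14, adjusted p = 0.0351 with an estimated correlation). Enzymes of immunometabolism rose too (14 of 18 tested genes higher, 14 adjusted over the list alone, adjusted p = 1.82e-06, adjusted p = 0.0187 with an estimated correlation). Genes of TNF receptors and response rose (15 of 20 tested genes higher and 2 lower, 15 and 2 adjusted over the list alone, adjusted p = 5.5e-07, adjusted p = 0.0433 with an estimated correlation). Targets of IRF1 and guanylate-binding proteins rose (19 of 25 tested genes higher and 1 lower, 19 and 1 adjusted over the list alone, adjusted p = 4.76e-07, adjusted p = 0.0433 with an estimated correlation). So did NF-kB subunits (5 of 5 tested genes higher, 5 adjusted over the list alone, adjusted p = 3.25e-05, adjusted p = 0.0468 with an estimated correlation). In all, 6227 genes were called, 3173 higher and 3054 lower. Of these calls 51.0% were higher, a share that was 15.2% with equal FPKM sums and went from 42.0% (quantile normalization) to 58.6% (the filter at 5 FPKM) over the 10 other settings.

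Compared with LPS alone, IFN-alpha before LPS changed 2721 genes, where TNF before LPS changed 5097. LGALS2 (6.78, SE 0.367, adjusted p = 9.79e-10), BRE-AS1 (5.30), the checkpoint receptor LAG3 (5.18), IFI27 (4.79), LGALS3BP (4.40) and IFITM1 (4.33) were higher. The monocyte chemokines CCL7 (-5.19) and CCL2 (-4.20), SERPINB2, an inhibitor of plasminogen activation (-5.28), APOC1 (-4.41) and CYP27A1 (-3.56) were lower. IL6 (-0.03, adjusted p = 0.982) and CXCL10 (-0.31, adjusted p = 0.766) were not called. Cholesterol biosynthesis genes were called at the preset correlation only (10 of 25 tested genes higher, 13 adjusted over the list alone, adjusted p = 6.76e-05, adjusted p = 0.630 with an estimated correlation), with SQLE at 2.27. No list was called here with an estimated correlation. Of the 2721 genes, 1414 were higher and 1307 lower, and 4419 were called with the block.

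The interaction of IFN-alpha with LPS was led by interferon-stimulated genes, which were already high before LPS. Of them, 51 of 59 tested genes were called lower (55 adjusted over the list alone, adjusted p = 7.67e-55, adjusted p = 0.0433 with an estimated correlation). IFIT1 was at 22.1 ± 19.3 FPKM in untreated cells, 880.2 ± 131 FPKM with IFN-alpha, 1069 ± 471 FPKM with LPS and 957 ± 94.4 FPKM (SD, n = 3) with both, and CXCL10 was at 15117 ± 7831 FPKM with LPS and 11090 ± 2656 FPKM with both. ADCY9, an adenylyl cyclase, responded to LPS more after IFN-alpha, at 109 ± 6.18 FPKM against 7.31 ± 0.957 FPKM, and so did FSCN1, which encodes the actin-bundling protein fascin, at 123 ± 17.4 FPKM against 17.7 ± 9.19 FPKM. In all, 972 genes were called, 467 higher and 505 lower, and 1967 with the block.

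IFN-alpha together with TNF raised part of the LPS-induced genes that TNF had lowered. IL6 reached 749 ± 326 FPKM (SD, n = 3) with all 3 treatments, against 18.7 ± 16.3 FPKM with TNF and LPS. Against TNF+LPS, IFI27 (6.79), IL23A, which encodes a subunit of interleukin 23 (6.29), IL6 (5.57), the interferon genes IFNB1 (4.97) and IFNL1 (4.81) and CXCL11 (4.83) rose most. The monocyte chemokine receptor CCR2 (-4.25), SLAMF8 (-4.11), APOC1 (-4.08), NKG7 (-3.71), FPR1 (-3.51) and S100A12 (-3.47) were lowest. CXCL10 rose (2.21) but stayed at 698 ± 252 FPKM, far below the 15117 ± 7831 FPKM of LPS alone. With IFN-alpha and TNF but no LPS its 3 libraries were already at 569, 1002 and 389 FPKM. With all 3 treatments they were at 912, 761 and 420 FPKM, so its increase need not be a return of the LPS response.

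The IRF family rose (4 of 9 tested genes higher, 4 adjusted over the list alone, adjusted p = 0.00158, adjusted p = 0.0433 with an estimated correlation), with IRF4 at 3.63, IRF8 at 2.48 and IRF1 at 2.26. At the preset correlation only, T cell ligands (9 of 17 tested genes higher, 9 adjusted over the list alone, adjusted p = 1.44e-05, adjusted p = 0.0509 with an estimated correlation) were called, among them CD70 (4.75) and TNFSF9 (4.25). The same held for inflammatory cytokines (12 of 23 tested genes higher, 13 adjusted over the list alone, adjusted p = 6.46e-06, adjusted p = 0.136 with an estimated correlation), with IL27 at 3.66. Feedback inhibitors were called likewise (20 of 31 tested genes higher and 2 lower, 20 and 2 adjusted over the list alone, adjusted p = 1.29e-07, adjusted p = 0.0929 with an estimated correlation), with DUSP2 at 3.17 and TRAF1 at 2.5. Macrophage identity genes were called lower in this way (2 of 40 tested genes higher and 14 lower, 3 and 14 adjusted over the list alone, adjusted p = 0.0193, adjusted p = 0.0616 with an estimated correlation), with CD163 at -2.69. Neutrophil markers had a median of 17.9 FPKM with all 3 treatments against 113 FPKM with TNF and LPS, with S100A9 at 801 FPKM against 3213 FPKM, and that list was not called (adjusted p = 0.152). In all, 3216 genes were called, 1799 higher and 1417 lower, and 4929 with the block but 954 with only the groups compared. Higher genes made up 55.9% of calls, 19.2% with equal FPKM sums, and from 48.5% (quantile normalization) to 65.8% (the 2-fold threshold) over the 10 other settings.

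Of the 558 LPS-induced genes that TNF lowered, 188 (33.7%) were called at least 2-fold higher with IFN-alpha, against 19.6% of the other LPS-induced genes. The TNF+LPS libraries enter both steps, so selection can widen this gap. In the held-out replicate numbers the median IFN-alpha effect was 0.58, 0.80 and 0.51 for the lowered genes and 0.50, 0.55 and 0.24 for the others. The largest of these increases were in IFI27, IL6, CXCL11, the nuclear receptor NR4A3 (4.34), the T cell ligand TNFSF9 (4.25), LINC00158 (4.10), NEURL3 (3.86), IL27, IRF4 and CXCL9 (3.56), and 7 of the 558 fell at least 2-fold. ITGAX (-1.50), ACTN1 (-1.53), MYOF (-1.70) and EMP1 (-2.01) fell further with IFN-alpha, EMP1 with an adjusted p of 0.0452, and CCL2 (-1.64, adjusted p = 0.0945) was not called. Among the 188 were 9 of the 9 feedback inhibitors that TNF had lowered, 5 of 8 inflammatory cytokines and 6 of 12 chemokines. So were 7 of 18 interferon-stimulated genes and 4 of 10 inflammasome and cell death genes, but 0 of 3 tissue remodelling and coagulation genes. Differences between lists in these shares were not tested. Set against LPS alone, 125 of the 188 were not called, 32 were still lower and 31 were higher, with a median of -0.05. The choice of the 188 used the same IFN+TNF+LPS libraries, so it raises this median by construction. If lowering by TNF and raising by IFN-alpha were independent among the 1788 LPS-induced genes, 134 would be expected. With quantile normalization 121 genes, with equal FPKM sums 72 and with the block 201 met the definition, and 164 of the 188 were still called higher with equal FPKM sums.

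**Figure D4:**
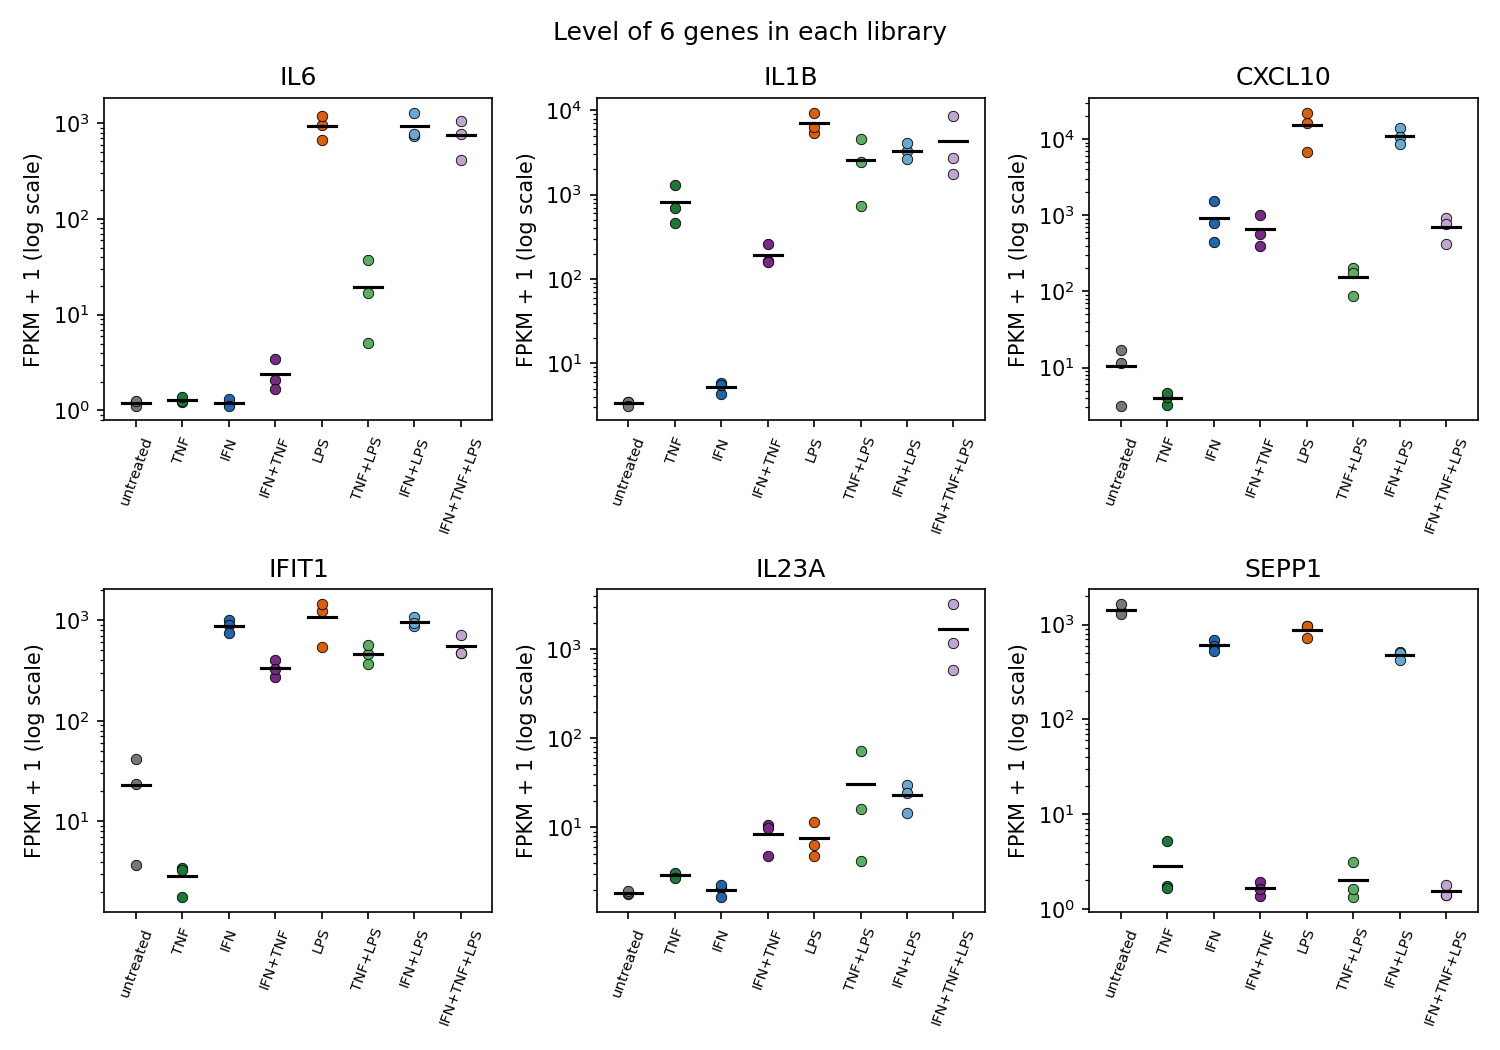
Each point is 1 library and each line the mean of 3, as FPKM + 1 on a log scale, for IL6, IL1B, CXCL10, IFIT1, IL23A and SEPP1 in the 8 groups. IL6 averages 941 FPKM with LPS, 18.7 with TNF and LPS, and 749 with all 3.

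The effect of LPS in cells given both cytokines was largest for BRE-AS1 (8.56, SE 0.618, adjusted p = 5.75e-09), IL6 (8.24), CCL20, which attracts lymphocytes and dendritic cells (7.87), PTGS2, which encodes cyclooxygenase 2 (7.41), IL23A (7.37) and TNIP3 (6.55). MYCL1 (-3.25), the kinase MAP3K14 (-2.95), KLHDC8B (-2.87), CCR2 (-2.79) and DUSP6 (-2.68) were lower. Guanylate-binding proteins and IRF1 targets rose (16 of 25 tested genes higher, 18 adjusted over the list alone, adjusted p = 5.49e-07, adjusted p = 0.0433 with an estimated correlation). Inflammatory cytokines were called at the preset correlation only (18 of 23 tested genes higher and 1 lower, 18 and 1 adjusted over the list alone, adjusted p = 6.16e-08, adjusted p = 0.0703 with an estimated correlation), with CSF3, which encodes the growth factor G-CSF, at 5.27. In all, 3829 genes were called, 2189 higher and 1640 lower, and 2511 with only the groups compared. The higher share of 57.2% was 13.2% with equal FPKM sums, and went from 42.1% (quantile normalization) to 72.7% (the 2-fold threshold) over the 10 other settings.

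Against LPS alone, cells given both cytokines before LPS had more IL23A (7.54, SE 0.700, adjusted p = 8.23e-08), MT1H (6.92), CLEC6A (6.60), MT1P2 (6.28), PTGES (6.15) and CLU (6.05). They had less SEPP1 (-9.17), FOLR2 (-8.73), F13A1 (-8.24), S100A4 (-7.65), RNASE1 (-7.12) and STAB1 (-6.90), and macrophage identity genes fell (3 of 40 tested genes higher and 29 lower, 3 and 29 adjusted over the list alone, adjusted p = 9.01e-09, adjusted p = 0.00126 with an estimated correlation). IL6 was not called (-0.40, adjusted p = 0.541), while CXCL10 (-4.34) and IL12B (-2.08) were lower and IFNB1 (3.59) and CCL5 (2.62) higher. In all, 5437 genes were called, 2855 higher and 2582 lower.

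Whether the IFN-alpha effect in TNF-treated cells differed with LPS was tested by its interaction. Interferon-stimulated genes had smaller effects with LPS (51 of 59 tested genes lower, 53 adjusted over the list alone, adjusted p = 1.84e-70, adjusted p = 0.0351 with an estimated correlation). Inflammatory cytokines went the other way at the preset correlation only (8 of 23 tested genes higher, 9 adjusted over the list alone, adjusted p = 3.9e-06, adjusted p = 0.122 with an estimated correlation), and IFNL1, listed at 0 in all 12 libraries without LPS, was at 0.153 ± 0.172 FPKM with TNF and LPS and 33.4 ± 14.6 FPKM (SD, n = 3) with all 3. In all, 691 genes were called, 367 higher and 324 lower, and 1501 with the block but 330 with only the groups compared. The higher share of 53.1% was 25.6% with equal FPKM sums, and went from 48.3% (a pseudocount of 0.1) to 60.7% (median centring) over the 10 other settings.

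Without LPS, the interaction of IFN-alpha with TNF called 1194 genes, 597 higher and 597 lower, and 2336 with the block. FPR1, which senses bacterial peptides, was at 307 ± 66.6 FPKM with TNF, 110.2 ± 36.9 FPKM with IFN-alpha and 21.7 ± 12.1 FPKM (SD, n = 3) with both, and its relative FPR2 at 58.8 ± 11.3 FPKM, 12.1 ± 4.49 FPKM and 12.1 ± 6.91 FPKM. NEURL3, a ubiquitin ligase, was at 0.123 ± 0.0208 FPKM, 2.42 ± 1.17 FPKM and 86.5 ± 21.4 FPKM. At the preset correlation only, pattern recognition receptors (7 of 26 tested genes lower, 10 adjusted over the list alone, adjusted p = 4.89e-05, adjusted p = 0.120 with an estimated correlation) and cholesterol biosynthesis genes (7 of 25 tested genes lower, 8 adjusted over the list alone, adjusted p = 4.57e-06, adjusted p = 0.562 with an estimated correlation) had smaller values together than the sum of both effects. So had neutrophil markers (2 of 9 tested genes lower, 3 adjusted over the list alone, adjusted p = 0.0108, adjusted p = 0.413 with an estimated correlation).

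The interaction of all 3 treatments called 100 genes, 52 higher and 48 lower, and 442 with the block. IL27, an interleukin with both activating and restraining roles, was at 341 ± 38.6 FPKM with LPS, 12.4 ± 1.64 FPKM with TNF and LPS, 328 ± 80.1 FPKM with IFN-alpha and LPS and 171 ± 35.3 FPKM (SD, n = 3) with all 3. IRF8, a transcription factor of myeloid cells, was at 679.6 ± 54.6 FPKM, 97.1 ± 11.4 FPKM, 553 ± 56.9 FPKM and 573 ± 226 FPKM. Without 1 library the count fell by more than 1.5 times for 12 libraries. It was 54 without untreated replicate 2, 63 and 64 without LPS replicates 2 and 3, 43 without TNF replicate 3, 65 and 60 without TNF+LPS replicates 2 and 3, 44 and 49 without IFN replicates 2 and 3, 53 and 58 without IFN+LPS replicates 2 and 3, and 54 and 50 without IFN+TNF replicates 2 and 3. With a pseudocount of 0.1 it was 47, and with replicate numbers 2 and 3 only 178. The higher share of 52.0% was 24.5% with equal FPKM sums, and went from 46.8% (a pseudocount of 0.1) to 60.7% (replicate numbers 2 and 3 only) over the 10 other settings.

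The median marker of T cells reached 1.29 FPKM, that of B cells 1.17 FPKM and that of natural killer cells 1.96 FPKM at most over the 8 groups. Neutrophil markers were higher, with medians from 5.13 FPKM in untreated cells to 113 FPKM with TNF and LPS, and lower medians where IFN-alpha was added to TNF, 13.1 FPKM without and 17.9 FPKM with LPS. Single markers stood out in the low lists: NKG7 reached 583 ± 210.0 FPKM with TNF, and IL7R, a T cell marker, was at 1.42 ± 0.694 FPKM in untreated cells and 699 ± 252 FPKM with LPS. Genes of heat shock and stress, a list fixed as a sign of RNA quality, had medians from 10.8 FPKM with IFN-alpha and 13.3 FPKM in untreated cells to 26.1 FPKM with IFN-alpha and TNF and 27.3 FPKM with IFN-alpha and LPS. XBP1 was at 66.3 ± 6.45 FPKM in untreated cells, 274 ± 30.7 FPKM with TNF and LPS and 837 ± 303 FPKM (SD, n = 3) with all 3. At the preset correlation only, this list was called higher in IFN+LPS vs IFN (7 of 18 tested genes higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.0325, adjusted p = 0.412 with an estimated correlation). So it was in the interactions of IFN-alpha with LPS (adjusted p = 0.0492, adjusted p = 0.453 with an estimated correlation) and with TNF (adjusted p = 0.00417, adjusted p = 0.237 with an estimated correlation). A stress response and RNA quality were not told apart here.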

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

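The tests of selection, scaling and a need for LPS below, and the split count of list tests with an estimated correlation, were chosen after the results were seen. The results of the first paragraphs are differences between effects, tested as interactions, and the classes of the last are defined by pairwise comparisons. In an interaction a positive value means an effect that was more positive, or less negative, in the presence of the other treatment. LPS alone lowered PDK4, CXCR4 and CD180, so their positive values with TNF below mark a smaller decrease.

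TNF with LPS gave 2240 called genes. The largest positive values were PDK4 5.03, CXCR4 4.80, MAF 4.52, CD180 4.46, TNFRSF21 4.44 and HS3ST2 4.26, and the largest negative values were IL1B -9.55, CCL4 -7.37, CXCL11 -7.27, TRAF1 -7.01, IL7R -6.42 and IL8 -6.41.

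IFN-alpha with LPS gave 972. BRE-AS1 5.10, HAMP 5.02, ADCY9 3.90, RANBP3L 3.82, FSCN1 3.75 and PDK4 3.53 were highest, PDK4 no longer called with a pseudocount of 0.1 (2.93, adjusted p = 0.0994). CCL8 -7.92, CXCL10 -6.89, RSAD2 -6.21, IFIT1 -5.87, IFIT2 -5.68 and APOBEC3A -5.36 were lowest.

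IFN-alpha with LPS after TNF gave 691. IFNB1 4.93, IL23A 4.84, IFNL1 4.81, IL6 4.72, CXCL3 4.03 and MFSD2A 3.86 were highest; IL23A was not called with only the groups compared (adjusted p = 0.0746) or with replicate numbers 2 and 3 only (4.13, adjusted p = 0.077). CCL8 -7.93, IFIT1 -6.67, RSAD2 -6.32, IFIT2 -6.01, IFIT3 -5.92 and MX1 -5.17 were lowest.

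IFN-alpha with TNF gave 1194. NEURL3 4.74, HS3ST2 4.49, CST7 4.37, ARMC9 4.27, NR4A3 4.18 and LSP1 4.16 were highest, and with replicate numbers 2 and 3 only CST7 (3.52), NR4A3 (3.64) and LSP1 (3.22) were not called. FADS2 -5.51, FPR1 -5.44, LGALS2 -4.94, CCR2 -4.68, ENPP2 -4.44 and FPR2 -4.24 were lowest. Without TNF replicate 1 FADS2 (-4.31) and ENPP2 (-3.96) were not called, nor was FADS2 without IFN replicate 3 (-5.23) or IFN+TNF replicate 2 (-4.71), nor ENPP2 with replicate numbers 2 and 3 only (-2.94).

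All 3 treatments together gave 100. IL1RN 6.04, IL27 5.03, IL6 4.75, CITED2 3.57 and IRF8 3.44 were among the highest, and KLHDC8B -3.60, SUCNR1 -3.40, NLRC4 -2.96, IDO2 -2.93, TRIB1 -2.92 and GYPC -2.60 were lowest. IL1RN kept its call only without TNF replicate 1 or 2, IFN+TNF replicate 2 or IFN+TNF+LPS replicate 1, with values from 5.48 to 6.34 where it lost it. CITED2 kept its call without replicate 1 of untreated, LPS, TNF+LPS, IFN+LPS or IFN+TNF, TNF replicate 2 or IFN+TNF+LPS replicate 3, and was otherwise between 3.21 and 3.74. TRIB1 kept its call without replicate 1 of untreated, LPS, TNF+LPS or IFN+TNF+LPS, TNF replicate 2 or IFN replicate 3, and was otherwise between -3.04 and -2.62. IL6 lost its call without untreated replicate 2 (4.70), LPS replicate 3 (4.56), TNF replicate 3 (4.70), IFN replicate 2 (4.68), IFN+LPS replicate 2 (4.60) or 3 (4.63), or IFN+TNF replicate 3 (4.52). SUCNR1 lost its call without TNF replicate 3 (-3.33), IFN replicate 2 (-3.39) or 3 (-3.33) or IFN+LPS replicate 2 (-3.21). With a pseudocount of 0.1 none of IL1RN (6.22), CITED2 (3.66), TRIB1 (-3.08), IL6 (3.88), SUCNR1 (-4.14) or KLHDC8B (-3.74) was called.

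Of 100 random splits of the libraries, the real one included, 5 gave as many genes as TNF with LPS (highest other 3887), 17 as IFN-alpha with LPS (4470), 6 as IFN-alpha with LPS after TNF (2791), 10 as IFN-alpha with TNF (3385) and 2 as all 3 treatments (1587). The splits were drawn again once, when the code was rearranged, and in the earlier draw the share for IFN-alpha with TNF was under 0.05, as was that for the 558 genes below within replicate numbers. Splits that moved labels only among libraries of 1 number gave as many in 15, 14, 13, 8 and 4 of 100, with highest counts of 6123, 4522, 2608, 3667 and 1033. Several of these counts are well above the real ones, which points to a structure of the samples: exchanged labels turn the large treatment effects into differences between effects. These splits therefore cannot say whether chance is excluded for any of the 5 interactions.

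IFN-alpha raised 188 LPS-induced genes that TNF had lowered: 1 of 100 splits gave as many (highest other 4), as did 1 of 100 for the 558 lowered genes (289), and 3 (436) and 5 (925) of 100 within replicate numbers, but these splits exchange treatments too and decide no more than those above. Selection on the shared TNF+LPS libraries would leave about 50% of the genes above 0 in a replicate number left out of the selection. The lowest share there was 94.7%. Of all genes lower with TNF, chosen without regard to IFN-alpha, 73.9%, 78.5% and 78.4% lay above 0 there, so 50% is a low baseline. The 94.7% shows that increases called in 2 numbers recurred in the third. It cannot say whether the shared libraries widened the overlap with genes that TNF lowered. With equal FPKM sums 87.2% of the 188 stayed called, and their median effect was 1.29 in place of 1.74, so that scaling did not remove the increase. The 188 had been chosen for an effect of at least 1, and this check set no size limit, so most could stay called under a moderate shift. Far fewer genes met the full definition with equal FPKM sums, so the part of the scaling in the size of the class stays open. An IFN-alpha effect that needed no LPS stays open for the class as a set. The effect with LPS was larger by medians of 0.60, 1.10 and 0.55 in the left-out numbers, with 63.2% of genes above 0 in number 1. The lowest median passed its bound of 0.5 by less than the spread of these medians. Without LPS the median effects there were 1.10, 0.81 and 0.54. Of the 188, 92 were called higher with IFN-alpha after TNF alone, and 63 were called positive in the interaction. Single members went both ways. After TNF, IFN-alpha raised IFI27, APOBEC3A and CXCL10 at least as much without LPS as with it, so their increase needed no LPS. IL6 rose more with LPS (interaction 4.72). That IFN-alpha restored part of the LPS response is a hypothesis, found and tested on the same libraries.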

How the results depend on the processing

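Most counts stayed within 1.5 times under most alternatives, and the exceptions follow; the cause was not tested unless stated. Equal FPKM sums, replicate numbers 2 and 3 only and leaving out the MHC region were chosen after seeing the data. Alternatives for read counts were not run, since the values are FPKM.

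With replicate number as a block more genes were called: IFN vs untreated 4018, IFN+TNF vs TNF 3865, TNF+LPS vs TNF 3832, IFN+LPS vs LPS 4419, IFN+TNF+LPS vs TNF+LPS 4929, and in the interactions TNF with LPS 3836, IFN with LPS 1967, IFN with LPS after TNF 1501, IFN with TNF 2336 and all 3 treatments 442. The block ended 6 list calls at the preset correlation and added 10. Requiring a log2 fold change of at least 1 lowers counts by construction: LPS vs untreated 3181, TNF vs untreated 1858, IFN vs untreated 1150, IFN+TNF vs untreated 2820, IFN+TNF vs TNF 989, TNF+LPS vs TNF 1018, IFN+LPS vs IFN 3222, IFN+TNF+LPS vs IFN+TNF 1629, TNF+LPS vs LPS 2306, IFN+LPS vs LPS 991, IFN+TNF+LPS vs TNF+LPS 1212, IFN+TNF+LPS vs LPS 2621 and TNF with LPS 1431. Without a size threshold, 1385 LPS-induced genes were lower with TNF and 549 higher again with IFN-alpha. With only the groups compared, which leaves fewer libraries, counts were IFN+TNF vs TNF 1293, TNF+LPS vs TNF 1187, IFN+TNF+LPS vs IFN+TNF 2511, IFN+TNF+LPS vs TNF+LPS 954 and IFN with LPS after TNF 330.

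Equal FPKM sums gave 5065 genes in TNF+LPS vs TNF, 6907 in IFN+TNF+LPS vs IFN+TNF, 163 in the interaction of all 3, and 182 and 72 genes lower with TNF and higher again. It moved the median of all genes to -0.80 in LPS vs untreated, -0.15 in IFN+TNF vs TNF, -0.40 in TNF+LPS vs TNF, -0.77 in IFN+LPS vs IFN, -0.59 in IFN+TNF+LPS vs IFN+TNF, 0.43 in TNF+LPS vs LPS, -0.34 in IFN+TNF+LPS vs TNF+LPS, 0.11 in IFN+TNF+LPS vs LPS, 0.40 in TNF with LPS, -0.18 in IFN with LPS after TNF and -0.22 in the interaction of all 3. In LPS vs untreated the median was -0.14 with median centring, -0.12 with quantile normalization and 0.13 with the filter at 5 FPKM, and the higher share of calls was 58.8% with that filter. For all 3 treatments quantile normalization gave 152, a pseudocount of 0.1 gave 47 and replicate numbers 2 and 3 only 178, and quantile normalization gave 121 genes higher again. List tests called were 51 with an estimated correlation and 293 with fry.

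Leaving out 1 library at a time gave, in the order of the bar plot, 5511 to 6160, 3024 to 3984, 2014 to 2730, 4872 to 5704, 1627 to 2479, 1607 to 2564, 5553 to 6340, 3066 to 3950, 4372 to 5240, 1947 to 2890, 2326 to 3285, 4796 to 5563, 1848 to 2370, 710 to 1063, 518 to 822, 887 to 1318 and 43 to 120 genes. Genes lower with TNF were 512 to 599, genes higher again 158 to 212, and list tests called 185 to 203.

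Among 939 called values of named genes, 144 lost the call under some alternative. Of the 31911 alternative values, 31106 kept direction and call, 803 lost the call and 2 reversed. The 2 reversals came with quantile normalization: IRF7 went from 1.10 to -0.21 in IFN+LPS vs IFN and IDO1 from 1.31 to -0.16 in IFN+TNF+LPS vs IFN+TNF. A further 3 values, not called before, also changed sign. With quantile normalization SOD2 went from -0.50 to 0.95 in TNF+LPS vs LPS and from 0.20 to -0.86 in IFN+TNF+LPS vs TNF+LPS, and with equal FPKM sums TLR4 went from 0.06 to -0.73 in IFN+TNF+LPS vs IFN+TNF. Depth is unknown and limits low values to an unknown degree.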

Other observations

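The choice of genes highest with all 3 treatments, and the tests of 1 common factor and of a scaling that fixes the middle of the distribution, were made after the results were seen. Called at least 2-fold higher with IFN-alpha, TNF and LPS than in each of the 7 other groups were 135 genes, and 145 with the block; 3 genes were at least 2-fold lower than in all 7. IL23A averaged 1671 ± 1386 FPKM (SD, n = 3) against 29.5 ± 35.9 in the next group, TNF+LPS. IFNB1, which encodes interferon beta, averaged 122 ± 81.4 FPKM against 9.67 ± 7.49 with LPS, and IFNL1, a type III interferon, 33.4 ± 14.6 against 2.75 ± 0.837 with IFN+LPS. The laminin gene LAMA3 had a smallest log2 fold change of 2.99 over the other groups, SEMA7A 2.69, IL12A, a subunit of interleukin 12, 2.32, and the T cell ligand CD70 2.24.

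For each of the 12 pairwise counts, 1 of the 10 splits of 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real value and the highest other were 6043 and 2 in LPS vs untreated, 3828 and 1 in TNF vs untreated, 2580 and 0 in IFN vs untreated, 5574 and 0 in IFN+TNF vs untreated, 2314 and 1 in IFN+TNF vs TNF, 2336 and 512 in TNF+LPS vs TNF, and 6227 and 0 in IFN+LPS vs IFN. They were 3829 and 7 in IFN+TNF+LPS vs IFN+TNF, 5097 and 0 in TNF+LPS vs LPS, 2721 and 1 in IFN+LPS vs LPS, 3216 and 1 in IFN+TNF+LPS vs TNF+LPS, and 5437 and 4 in IFN+TNF+LPS vs LPS. Among the 4 splits that part all 3 pairs of equal number, the highest other was 0, except 1 and 4 in the last comparisons with all 3 treatments. For list tests at the preset correlation, 60 of 100 splits gave at least 192 calls (highest other 261), and 41 of 100 splits within numbers (highest other 242). With an estimated correlation 1 of 100 gave the 51 calls (highest other 1). These splits exchange treatments, so they show at most whether the labels matter at all. They favor neither version of the test and cannot weigh chance for a single list.

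The summed FPKM rose from 328387 to 670281 with LPS while the median gene moved little, by 0.13 with the filter at 5 FPKM, and from 3.53 to 3.69 on the log2 scale over genes at 1 FPKM or more in all libraries. A factor common to all genes would by itself have raised the median as well, so it is not the whole cause of this rise in the deposited values; that 50.1% of the genes called with LPS were lower restates this, and the share follows the scaling, with 6911 of 8172 calls lower with equal FPKM sums. The 100 genes with the largest rise carried 65.9% of the net rise, between the bounds set for few and many genes, with CCL4 at 6.34%, SOD2 at 4.57% and CXCL10 at 4.42%. A scaling that fixes the middle of the distribution stays open, since the median log2 fold change of -0.0237 could then hide a change in total RNA. No biological explanation was tested.

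The libraries numbered 1 stood apart in every group, with 357 genes at least 2-fold different, 79.3% of them higher in number 1. The median over tested genes was 7.24 to 7.63 FPKM in libraries numbered 1 and 5.76 to 6.24 FPKM in numbers 2 and 3. A shift of genes in general thus enters this share, and its source was not tested. Gene length is argued against by a Spearman correlation of 0.0627 across genes, which are not independent replicates. Markers of other cell types deviated by -0.62 against all genes, less than the bound set against RNA from other cells in number 1, but that bound was one-sided and therefore wrong, since more such RNA in numbers 2 and 3 would give the same value. The lists also went both ways, with medians of 0.79 for 3 erythroid and 0.18 for 6 dendritic cell markers, against 0.16 for all genes, and -0.59 for T cell, -0.65 for natural killer cell and -0.67 for neutrophil markers, so RNA from other cell types stays open. A difference between donors and one between batches were not told apart here, since the labels give neither.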
